A study of Homo sapiens with 29 samples.

How the data were processed

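Total RNA of MCF-7 cells was labelled and hybridised to 29 Affymetrix arrays with 22277 probe sets each. Per the labels the cells stood in steroid-stripped medium and were transfected with siRNA pools by a lipid reagent. The values deposited by the authors are normalized log2 signals, up to 14.65, with 34 values of exactly 0 in 11 probe sets, 3 of which stand for tested genes. The authors' normalization method is not given in the sources used here. The quartiles of the arrays are close but not identical. Detection calls were not used here, and the number of arrays limits the precision.

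The platform table names genes for 20113 probe sets, of which 19070 name 1 gene and 1043 name several; 2164 probe sets are not in the table. Probe sets naming several genes or none were left out of the gene tests because their signal cannot be given to 1 gene. Gene identifiers were matched to current symbols for 19058 probe sets, and 12 kept the old symbol. Of the 4310 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 11963 genes. No gene was filtered out for a low level.

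The 8 groups were taken from the sample labels. A model with 1 mean per group and no batch term was fitted to the log2 values of each gene with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 21 residual degrees of freedom), with genes called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The groups share 1 estimate of the spread because each has only 3 or 4 arrays. Comparisons of siRNAs average the difference in untreated and in E2-treated cells with equal weight, and the interaction of the paralogs is both siRNAs minus SAFB1 siRNA minus SAFB2 siRNA plus control. Each comparison, the 22 gene lists, the rule for named genes and most alternatives were set before the data were examined.

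The lists were tested with limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 22 lists of a comparison. They held estrogen-induced, estrogen-repressed, proliferation, interferon-response, antigen-presentation, cytokine and chemokine, NF-kappa-B target, pro-apoptotic, anti-apoptotic, p53 target, unfolded protein response, heat shock, cholesterol synthesis, hypoxia, TGF-beta target, SAFB family and RNA processing, histone, siRNA machinery and RNA sensing, luminal, basal and mesenchymal, leukocyte and stromal, and ribosomal protein genes. Some genes stand in several lists. The lists were planned for the 3 siRNA comparisons and E2 in control cells; their tests in the direct comparison of SAFB1 and SAFB2 siRNA and in the interactions were added after seeing the data.

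Named genes were the 10 called genes with the largest rise and the 10 with the largest fall, among genes with a mean level above the median of all genes (8.58) and, for siRNAs, the same sign with and without E2; up to 4 members with the smallest p of each list that passed camera; and SAFB and SAFB2. For interactions they were the 5 called genes with the largest value in each direction, or the 3 with the smallest p if none was called. Where a fold is given for a fall it is the inverse of the ratio.

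Overlaps between siRNAs were compared with groups without effect simulated on the same controls in 20 rounds and with the control arrays divided between the comparisons in 18 ways. Single values were compared by two-sided exact permutation tests. The methods were tested on simulated data with the genes' own spread and run effects, where 200 genes were changed. For SAFB1 siRNA 71.6% of changes of 0.5 log2 and 97% of changes of 1 log2 were recovered, with 2.19% false among the calls, and for E2 in control cells 38.8% and 92.5%. With a term for the run 7.62% of the simulated calls for SAFB1 siRNA were false, above the nominal rate. In the interaction of E2 with SAFB1 siRNA 11.9% of changes of 0.5 log2 and 77.6% of changes of 1 log2 were recovered. Camera with the preset correlation found 3 of 3 simulated lists shifted by 0.5 log2 and called 0 others. Apart from run effects the simulated noise was independent between genes, so this does not give the false rate in the real arrays. Other splits of the real arrays passed a median of 6, 4, 6 and 4 of 22 lists for SAFB1, SAFB2, both siRNAs and E2 in control cells.

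Letters and numbers in the sample titles were checked as possible batches on the deviations from group means. Arrays of the same run of title numbers had a median correlation of 0.5 and 28 of 29 arrays fitted best with their own run. The replicate letter had a median of 0.323 and 17 of 29, so only the run is given beside the results. Letters A and B each coincide with a whole run, so letter and run differ only for letters C and D. The alternatives tried were terms for the letter and the run, quantile normalization, centring on array medians, an offset of 32, leaving out dim genes, other uses of several probe sets, array weights, eBayes with trend and robust, a 1.5-fold limit, only the groups compared, each arm alone, and each array left out in turn. Alternatives added after seeing the data were leaving out the pair of arrays with title numbers 15 and 16, blocks of 4 title numbers, the runs that hold all 8 groups, leaving out title numbers 17 to 19, each run alone, and RNA quality in pairs of the same run and treatment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.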

Results

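Expression was measured on 29 Affymetrix arrays of MCF-7 cells, an estrogen receptor-positive human breast cancer cell line kept in medium stripped of steroids. The cells carried a non-targeting control siRNA, a pool of siRNAs against SAFB1 (gene SAFB), a pool against SAFB2, or both pools, and were left untreated or given estradiol (E2) at a dose and for a time not given in the sources used here. SAFB1 and SAFB2 are paralogous nuclear proteins, encoded by neighbouring genes on chromosome 19, that bind DNA and RNA and act as corepressors of the estrogen receptor. There were 3 arrays each of control siRNA, control siRNA with E2 and SAFB1 siRNA with E2, and 4 arrays of each of the other 5 groups. Array medians lay between 8.23 and 8.30 on the log2 scale, and the number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Numbers in the sample titles fall into 4 runs of 8 (1 to 8, 9 to 16, 17 to 24 and 25 to 32), by which arrays of the same group differed, so the count of genes in each comparison is also given with a term for the run. The run 9 to 16 holds no control array. Pairs of an untreated and an E2-treated array were formed within runs. In the runs 1 to 8 and 9 to 16 each pair joins the replicate letters C and D. In the other runs the arrays of a pair share a letter. In each run control and SAFB1 siRNA have numbers among the first 4, and SAFB2 and both siRNAs among the last 4. Differences of SAFB2 or both siRNAs from control or SAFB1 siRNA therefore also span these parts of a run, which a term for the run does not remove. Such differences exist: the actin 3-prime minus 5-prime value averaged 0.26 in numbers 1 to 4 and 0.69 in 5 to 8, and 0.50 in 25 to 28 and 0.33 in 29 to 32. On the first component of the deviations from group means, numbers 17 to 19 lay at −17.1 to −9.35 and 21 to 24 at 2.04 to 7.70, so a term for the run describes that run poorly and counts without 17 to 19 are given where they differ by over 1.5 times. SAFB1 siRNA against control, both against SAFB2 siRNA, the interactions and E2 are compared within these parts or cancel them. Each siRNA effect below is the mean of the difference from control siRNA in the untreated and the E2-treated cells.

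The first question was how far each siRNA lowered its own target and its paralog. SAFB fell by 0.93 ± 0.10 on the log2 scale (SE, n = 7 against 6 control arrays) with SAFB1 siRNA, to 52.5% of control (limma adjusted p = 6.76e-07), and by 1.00 ± 0.10 (n = 8 against 6) with both siRNAs, to 50.1%. Its difference from control with SAFB2 siRNA was 0.00 ± 0.10. SAFB2 fell by 0.53 ± 0.08 with SAFB2 siRNA, to 69.4% of control (limma adjusted p = 0.000117), and by 0.42 ± 0.08 with both siRNAs, to 74.8%. In cells given SAFB1 siRNA, SAFB2 rose to 132% of control, a difference of 0.40 ± 0.08 (limma adjusted p = 0.00137). In untreated cells SAFB had a mean level of 10.43 ± 0.26 (SD, n = 3) with control siRNA and 9.44 ± 0.12 (n = 4) with SAFB1 siRNA, while SAFB2 had 8.85 ± 0.03 (n = 3) with control siRNA and 8.30 ± 0.21 (n = 4) with SAFB2 siRNA. Other probe sets differed less. The other probe set of SAFB2 showed 0.04 ± 0.07 with SAFB1 siRNA (adjusted p over all probe sets = 0.793) and −0.28 ± 0.06 with SAFB2 siRNA, and the other SAFB probe sets showed −0.47 (adjusted p = 0.0829) and −0.03 (adjusted p = 0.858) with SAFB1 siRNA. With a term for the run these SAFB probe sets showed −0.39 (limma adjusted p over all probe sets = 0.00718) and −0.06 (0.53).

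**Figure D1:**
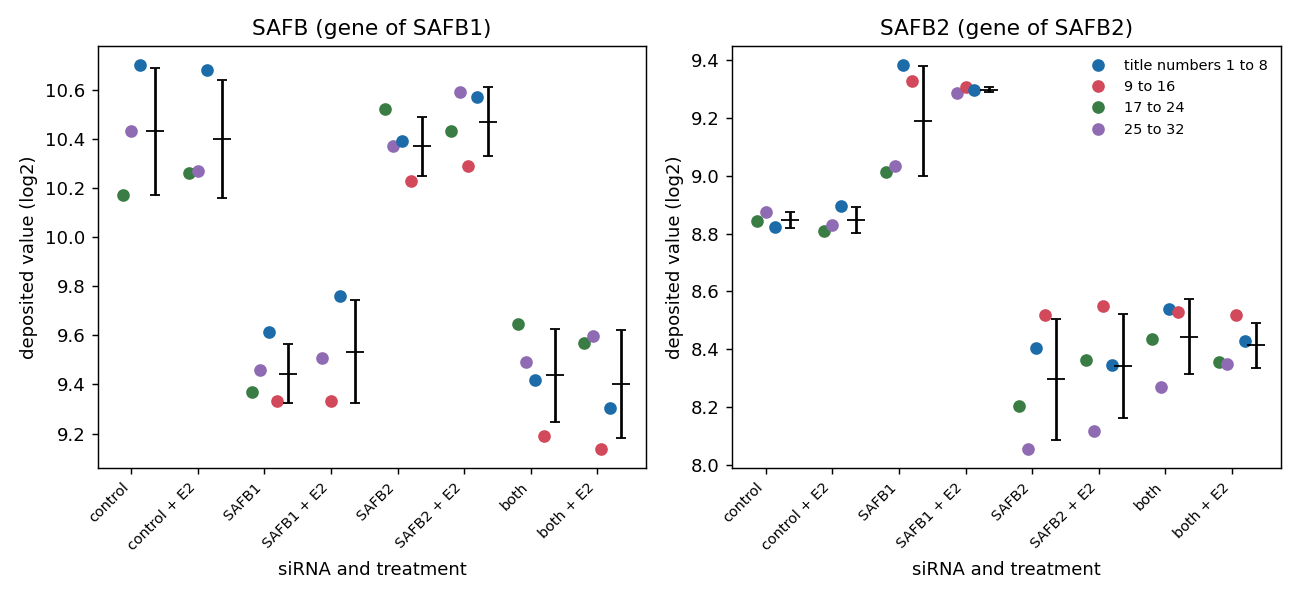
Deposited log2 value (vertical axis) of the probe set used for SAFB (left) and SAFB2 (right) in each of the 29 arrays, by siRNA and treatment (horizontal axis). Points are arrays coloured by run of title numbers, bars beside them are group means ± SD, and in untreated cells SAFB averages 10.43 with control siRNA and 9.44 with SAFB1 siRNA.

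SAFB1 siRNA changed 1041 of 11963 genes in limma (655 higher, 386 lower), 79 of them at least 2-fold, and 78 of these 79 rose. The largest rise among well-expressed genes was that of S100P, a calcium-binding protein (9.22-fold, log2 3.20 ± 0.45, n = 7 against 6). CD74, the invariant chain of MHC class II, rose 8.91-fold (3.15 ± 0.21), HLA-DPA1, an MHC class II chain, 8.25-fold (3.04 ± 0.19), and HMOX1, which breaks down heme, 8.36-fold (3.06 ± 0.25). Each of these 4 genes was higher in 5 of 5 comparisons of arrays of the same run and treatment. After SAFB itself the largest falls among well-expressed genes were in PVALB, a calcium-binding protein (−0.86 ± 0.15), CBX5, the heterochromatin protein HP1-alpha (−0.83 ± 0.09), HS1BP3 (−0.81 ± 0.20), and REEP1 (−0.71 ± 0.16). FASN, the fatty acid synthase, changed by −0.67 ± 0.16, the growth factor receptor FGFR4 by −0.66 ± 0.14, the DNA helicase HELLS by −0.66 ± 0.11 and PHGDH, which opens serine synthesis, by −0.64 ± 0.08.

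Of 35 measured interferon-response genes, 19 rose, 0 fell and 16 did not pass (22 rose adjusted over the list alone), among them ISG20, an RNA exonuclease (5.86-fold), TRIM22 (4-fold, limma adjusted p = 1.79e-12) and HERC5, the ligase of ISG15 (3.78-fold). Of 23 antigen-presentation genes, 15 rose, 0 fell and 8 did not pass (17 rose adjusted over the list alone), including HLA-DRA (3.82-fold), the immunoproteasome subunit PSMB9 (1.86-fold) and HLA-DMA (1.84-fold). Of 29 cytokines and chemokines, 13 rose and 16 did not pass, such as the chemokines CX3CL1 (4.45-fold), CCL5 (4.16-fold) and CCL2 (4.14-fold) and the cytokine LTB (5.86-fold); adjusted over the list alone, 13 rose and 1 fell. Of 34 proliferation genes, 20 fell, 0 rose and 14 did not pass (28 fell adjusted over the list alone), including the replication helicase subunit MCM3 (−0.52 ± 0.09), the ribonucleotide reductase subunit RRM2 (−0.43 ± 0.08), thymidine kinase TK1 (−0.41 ± 0.08) and the mitotic kinase AURKA (−0.36 ± 0.04). Of 20 p53 targets, 6 rose and 14 did not pass (10 rose and 1 fell adjusted over the list alone), among them the pro-apoptotic PMAIP1 (2.22-fold), the stress gene GADD45A (1.72-fold) and the cell cycle inhibitor CDKN1A (1.66-fold). These 5 lists passed camera with the preset correlation (adjusted p = 5.11e-22, 2.14e-18, 4.81e-10, 3.78e-18 and 7.16e-07) and with an estimated correlation (adjusted p = 0.00197, 0.00879, 0.0256, 0.00197 and 0.00197).

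In 9 further lists camera passed with the preset correlation of 0.01 and, without a term for the run, not with an estimated one. NF-kappa-B targets were higher (adjusted p = 5.64e-08, and 0.0575 with an estimated correlation), and 8 of 19 rose and 11 did not pass (9 rose and 1 fell adjusted over the list alone), such as the inhibitors TNFAIP3 (2.58-fold) and NFKBIA (2.24-fold). Pro-apoptotic genes were higher (0.0081, and adjusted p = 0.0673 with an estimated correlation), with 3 of 32 risen, among them the death ligand TNFSF10 (2.25-fold) and its receptor TNFRSF10B (1.69-fold), and 1 fallen, the mitochondrial flavoprotein AIFM1 (−0.30 ± 0.08). Anti-apoptotic genes were also higher (0.0118, and adjusted p = 0.0755 with an estimated correlation), with CFLAR (1.38-fold) and BAG1 (1.45-fold) risen and BIRC5, which is also a mitotic gene, lower by −0.55 ± 0.14. With an estimated correlation the adjusted p was 0.185 for the unfolded protein response (6 of 25 rose, such as ATF3 at 2.19-fold), 0.0758 for cholesterol synthesis (2 of 18 rose, HMGCS1 at 1.66-fold and NSDHL at 1.18-fold), 0.214 for luminal epithelial genes (2 of 19 rose) and 0.287 for estrogen-repressed genes (3 of 14 rose and 1 fell). It was 0.214 for genes of the siRNA machinery and RNA sensing, of which 6 of 19 rose, such as the sensor IFIH1 (1.79-fold), and 2 fell, with a mean difference of 0.15 and a median of −0.02. It was 0.452 for histones, of which 3 of 24 fell, such as H1-2 (−0.64 ± 0.15), and H3C2 rose by 0.32 ± 0.08. The remaining lists did not pass camera with the preset correlation (estrogen-induced adjusted p = 0.229, heat shock 0.493, hypoxia 0.923, TGF-beta targets 0.295, SAFB family and RNA processing 0.912, basal and mesenchymal 0.537, ribosomal proteins 0.676, leukocyte and stromal markers 0.113). With a term for the run, 2935 genes passed (1452 higher, 1483 lower), among them all 1041. The adjusted p with an estimated correlation was then 0.0372 for NF-kappa-B targets and 0.0426 for pro-apoptotic genes. The preponderance of rises, 62.9% of the genes called, was then 49.5%.

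**Figure D2:**
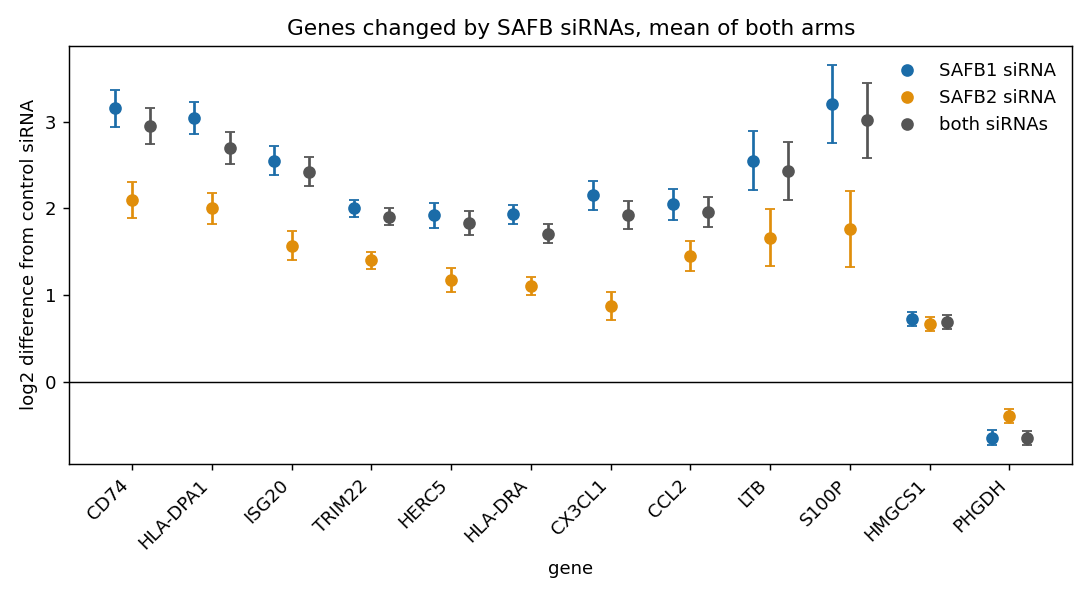
Log2 difference from control siRNA (vertical axis), mean of untreated and E2-treated cells, for 12 genes (horizontal axis) with SAFB1 siRNA (7 arrays), SAFB2 siRNA (8 arrays) or both siRNAs (8 arrays) against 6 control arrays. Bars are limma standard errors; CD74 stands at 3.15, 2.09 and 2.95 for the 3 treatments.

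SAFB2 siRNA changed 197 genes (170 higher, 27 lower). CD74 rose 4.27-fold (log2 2.09 ± 0.21, n = 8 against 6), HLA-DPA1 4.01-fold (2.00 ± 0.18), S100P 3.39-fold (1.76 ± 0.44), ISG20 2.98-fold (1.57 ± 0.17) and TRIM22 2.64-fold (1.40 ± 0.10, limma adjusted p = 2.76e-09), each in 6 of 6 comparisons within a run. OPTN, an autophagy receptor, rose 2.34-fold and the complement factor CFB 2.89-fold. The largest falls were in ACTG2, a smooth muscle actin (−1.03 ± 0.14), NUDT3 (−0.54 ± 0.10), SAFB2 itself, and TFF3, a secreted trefoil peptide (−0.50 ± 0.12). Of 35 interferon-response genes, 11 rose and 24 did not pass (19 rose adjusted over the list alone), and of 23 antigen-presentation genes 8 rose and 15 did not pass (14 rose adjusted over the list alone). Of 18 cholesterol synthesis genes, 3 rose and 15 did not pass (7 rose and 1 fell adjusted over the list alone): HMGCS1, which makes HMG-CoA (1.59-fold), MSMO1 (1.42-fold) and ACAT2 (1.33-fold). These 3 lists passed camera with the preset correlation (adjusted p = 5.93e-20, 4.37e-18 and 1.83e-06) and with an estimated one (0.00372, 0.0126 and 0.00171). Cytokines and chemokines had 5 of 29 members risen, such as CCL2 (2.74-fold), and NF-kappa-B targets 5 of 19, such as TNFAIP3 (1.91-fold), with adjusted p = 0.0977 and 0.117 with an estimated correlation. Genes of the siRNA machinery and RNA sensing (3 of 19 rose, such as IFIH1 at 1.57-fold) had adjusted p = 0.214 with an estimated correlation, anti-apoptotic genes 0.0977, histones 0.544 and leukocyte and stromal markers 0.505, and no member of the last 3 lists passed. Of 34 proliferation genes 0 passed in limma without a term for the run, and with it 1 was higher and 5 lower (camera adjusted p = 0.127 and 0.271). A term for the run gave 2570 genes (1287 higher, 1283 lower), and 958 without title numbers 17 to 19. With the run term and all arrays the adjusted p with an estimated correlation was 0.0714 for interferon-response, 0.0885 for antigen-presentation and 0.0551 for cholesterol synthesis genes. Without control replicate B, 121 genes passed. Across the 197 genes, the difference of both siRNAs from SAFB1 siRNA, which spans the same parts of a run, had a slope of −0.06 on the SAFB2 siRNA effect (−0.28 to 0.14 in 7 pairs within runs), where a shift of the last 4 numbers that adds alike whatever the siRNA would by itself give about 1.

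With both siRNAs 909 genes changed (580 higher, 329 lower). S100P rose 8.08-fold (log2 3.02 ± 0.44, n = 8 against 6), CD74 7.73-fold (2.95 ± 0.21), HLA-DPA1 6.49-fold (2.70 ± 0.18), HMOX1 5.02-fold (2.33 ± 0.24) and TRIM22 3.75-fold (1.91 ± 0.10, limma adjusted p = 2.42e-12), each in 6 of 6 comparisons within a run. After SAFB the largest falls were in the zinc importer SLC39A4 (−0.79 ± 0.23), H1-2 (−0.75 ± 0.14) and ACTG2 (−0.74 ± 0.14). Interferon-response genes had 17 of 35 members risen (22 adjusted over the list alone), antigen-presentation genes 13 of 23 (17), cytokines and chemokines 13 of 29 (13, and 1 fell) and p53 targets 6 of 20 (8), and the others in these lists did not pass. Of 34 proliferation genes, 21 fell and 13 did not pass (28 fell adjusted over the list alone), such as AURKA (−0.36 ± 0.04) and CCNB1, a mitotic cyclin (−0.27 ± 0.05). These 5 lists passed camera with an estimated correlation too (adjusted p = 0.00223, 0.00864, 0.0386, 0.00223 and 0.00223). Another 9 lists passed with the preset correlation alone, with adjusted p from an estimated correlation of 0.0553 for NF-kappa-B targets (8 of 19 rose, 1 fell), 0.191 for histones (5 of 24 fell) and 0.0912 for cholesterol synthesis (1 of 18 rose). It was 0.143 for the unfolded protein response (4 of 25 rose), 0.143 for pro-apoptotic genes (3 of 32 rose), 0.105 for anti-apoptotic genes (2 of 14 rose, 1 fell), 0.145 for the siRNA machinery and RNA sensing (6 of 19 rose, 2 fell), 0.191 for luminal genes (1 of 19 rose) and 0.233 for estrogen-repressed genes (4 of 14 rose, 1 fell). A run term gave 3485 genes (1687 higher, 1798 lower), and 2288 without title numbers 17 to 19. With the run term and all arrays the adjusted p of the cytokines and chemokines with an estimated correlation was 0.0568.

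The siRNAs shared many of these genes. Of 170 genes higher with SAFB2 siRNA, 153 were also higher with SAFB1 siRNA, where independent lists would share 9.31, and of 27 lower genes 20 were shared (0.871). SAFB1 siRNA and both siRNAs shared 510 higher genes (31.8 for independent lists) and 245 lower genes (10.6), and SAFB2 siRNA and both siRNAs shared 159 (8.24) and 24 (0.743). Because the treatments share the control arrays, groups without any effect were simulated on those controls. Across genes, which are not independent replicates, the SAFB1 and SAFB2 siRNA effects had r = 0.812 and a covariance of 0.0313, against 0.554 and 0.0074 in the simulation. It shared 0 called genes in limma, but groups without effect give few calls, so this count cannot tell how much sharing the common controls create. For SAFB1 siRNA and both siRNAs r was 0.947 and the covariance 0.0489, against 0.551 and 0.00738. With run effects added to the simulation its r was 0.712 for both pairs, with covariances of 0.00756 and 0.00755. With the control arrays divided between the comparisons, SAFB1 and SAFB2 siRNA shared a mean of 59.7 higher genes over 18 divisions, against 2.2 for independent lists, and the covariance was 0.0248. Shared lower genes were then 3.61 (0.339 for independent lists), and 42.8 (2.01) for SAFB1 siRNA and both siRNAs.

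Direct comparison of the siRNAs asked where the effects of the pools differ. The pools lowered their targets unequally (SAFB to 52.5% and SAFB2 to 69.4% of control), so a difference between pools need not be one between the paralogs. With SAFB1 siRNA 196 genes differed from SAFB2 siRNA (112 higher, 84 lower). HMOX1 was 5.83-fold higher (log2 2.54 ± 0.23, n = 7 against 8, limma adjusted p = 3.83e-07), GDF15, a stress-induced cytokine, 2.45-fold (1.29 ± 0.22), CX3CL1 2.43-fold (1.28 ± 0.15), CD74 2.09-fold (1.06 ± 0.20) and HLA-DPA1 2.06-fold (1.04 ± 0.18), in 7 of 7 comparisons within a run. The lower genes included the ubiquitin ligase subunit SKP2 (−0.56 ± 0.09), DTL (−0.51 ± 0.13), the replication licensing factor CDC6 (−0.47 ± 0.11) and the helicase BLM (−0.46 ± 0.11). Of 34 proliferation genes, 10 were lower and 24 did not pass (26 lower adjusted over the list alone), and of 20 p53 targets 5 were higher and 15 did not pass (6 adjusted over the list alone). Both lists passed camera with the preset correlation (adjusted p = 4.17e-29 and 2.75e-08) and with an estimated one (0.000302 and 0.000368). Interferon-response genes (4 of 35 higher, 10 adjusted over the list alone) and antigen-presentation genes (3 of 23, 7 adjusted over the list alone) passed with the preset correlation (2.31e-09 and 1.83e-07), but with an estimated correlation their adjusted p was 0.0683 and 0.119. With a term for the run 972 genes passed. Leaving out single arrays gave 115 without SAFB1 replicate A, 117 without SAFB1 B, 110 without SAFB1 with E2 B, 120 without SAFB1 with E2 C, 130 without SAFB2 A, 125 without SAFB2 C and 120 without SAFB2 with E2 D.

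Whether the double knockdown equalled the sum of the single ones was tested by an interaction of the paralogs, in which 68 genes passed (5 higher, 63 lower). CD74 with both siRNAs was 4.91-fold below the sum of the single effects (−2.30 ± 0.29, all 29 arrays, limma adjusted p = 4.56e-05), HLA-DPA1 5.09-fold (−2.35 ± 0.25), TCIM 6.35-fold (−2.67 ± 0.37), the decoy receptor TNFRSF11B 3.75-fold (−1.91 ± 0.30) and the calprotectin subunit S100A8 3.68-fold (−1.88 ± 0.31). The 5 genes above the sum were CSTA, a protease inhibitor (0.93 ± 0.19), FAM168B (0.38 ± 0.09), MAGED2 (0.36 ± 0.08), EYA1 (0.30 ± 0.07) and VOPP1 (0.30 ± 0.06). Of 35 interferon-response genes 6 were below the sum and 29 did not pass (13 adjusted over the list alone), of 23 antigen-presentation genes 5 and 18 (11), and of 18 cholesterol synthesis genes 1 and 17 (3). These lists passed camera with the preset correlation (1.14e-19, 1.14e-19 and 4.15e-06) and with an estimated one (adjusted p = 0.00412, 0.00865 and 0.00269). Between both siRNAs and SAFB1 siRNA directly, 1 gene passed in limma, SAFB2 itself (−0.82 ± 0.07, nominal count 91 at an unadjusted p under 0.05). By contrast 88 genes differed between both siRNAs and SAFB2 siRNA (36 higher, 52 lower). With the run term these counts were 2, SAFB2 and UCHL3 (adjusted p = 0.0106), and 449 (206 higher, 243 lower). Without title numbers 15 and 16 they were 1 and 76. For both siRNAs against SAFB1 siRNA the unadjusted count was 521 with the run term and 581 without title numbers 15 and 16. With both changes it was 720, and 1 gene passed. Chance alone gives more than 91, 0.05 of 11963 genes. The near absence of calls therefore does not show that both siRNAs act like SAFB1 siRNA. The run term gave 410 genes in the interaction (102 higher, 308 lower). Of single arrays left out, 44 passed without control replicate B and 45 without SAFB1 replicate B. Genes above the sum then ranged from 2 (for example without control with E2 B) to 8 (without both siRNAs D).

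E2 in control cells tested the estrogen response with SAFB proteins present, and changed 78 genes (29 higher, 49 lower). Of these, 36 changed at least 2-fold. PTGES, the prostaglandin E synthase, rose 3.83-fold (log2 1.94 ± 0.46, n = 3 against 3, limma adjusted p = 0.0457), IGFBP4, which binds insulin-like growth factors, 3.06-fold (1.61 ± 0.35), ELOVL2, a fatty acid elongase, 2.88-fold (1.53 ± 0.32), SIAH2, a ubiquitin ligase, 2.51-fold (1.33 ± 0.29) and the chemokine CXCL12 2.03-fold (1.02 ± 0.22), each in 3 of 3 pairs of arrays. The matrix protein EFEMP1 fell (−1.50 ± 0.26), as did the ephrin EFNA1 (−1.31 ± 0.24), the cell cycle gene CCNG2 (−1.20 ± 0.28) and the receptor tyrosine kinase ERBB2 (−1.03 ± 0.20). Of 28 known estrogen-induced genes, 8 rose and 20 did not pass (14 rose adjusted over the list alone), and of 14 estrogen-repressed genes 4 fell and 10 did not pass (7 adjusted over the list alone). With an estimated correlation their adjusted p was 0.0878 and 0.0731. Of 35 interferon-response genes, TRIM22 (−0.71 ± 0.15) and OAS1 (−0.55 ± 0.12) fell and 33 did not pass (8 fell adjusted over the list alone; adjusted p = 0.0731 with an estimated correlation). Camera with the preset correlation passed these 3 lists (adjusted p = 4.92e-18, 1.01e-07 and 1.83e-11) and 4 more with no member called, in which antigen-presentation, histone and luminal genes were lower and leukocyte and stromal markers higher (adjusted p = 0.618, 0.618, 0.26 and 0.424 with an estimated correlation). A term for the run gave 680 genes (209 higher, 471 lower), but 1 without title numbers 17 to 19. Without single arrays 2 genes passed without control replicate A, 10 without control B, 6 without control C, 1 without control with E2 B, 2 without control with E2 D and 0 in limma (827 at an unadjusted p under 0.05) without control with E2 A.

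The last question was whether the estrogen response depends on SAFB proteins. E2 changed 32 genes with SAFB1 siRNA (28 higher, 4 lower), 191 with SAFB2 siRNA (117 higher, 74 lower) and 0 with both siRNAs in limma (228 at an unadjusted p under 0.05). The interaction of E2 with each siRNA, which tests these differences, passed for 0 genes in limma in each of 3 cases (140, 155 and 145 at an unadjusted p under 0.05, and 481, 458 and 485 with the run term, where 0 passed too). Chance alone gives more than each of these counts, 0.05 of 11963 genes. The absence of calls therefore does not show that the response is independent of SAFB proteins. In simulated data the interaction with SAFB1 siRNA recovered 11.9% of changes of 0.5 log2. The smallest p-values were those of MSTN (−1.58 ± 0.41), CKM (−0.44 ± 0.14) and CALCB (0.77 ± 0.25) for SAFB1 siRNA, TNFSF15 (−0.63 ± 0.18), ID2B (−0.56 ± 0.16) and TAF1A (0.53 ± 0.16) for SAFB2 siRNA, and TBC1D9 (0.59 ± 0.15), RTP4 (0.88 ± 0.24) and HLA-DRB6 (−0.96 ± 0.27) for both siRNAs, with an adjusted p of 1. Camera passed 3, 4 and 5 lists with the preset correlation and 0 with an estimated one. Across the 78 genes changed by E2 in control cells, which are not independent replicates, the E2 effect with SAFB1 siRNA had a slope of 0.81 on that in control cells and was smaller in 73 of 78. The slope was 0.922 for SAFB2 siRNA (63 of 78 smaller) and 0.414 for both siRNAs (78 of 78). Genes picked for a large effect in control cells tend to be smaller elsewhere, and the slopes have no test of their own. On the fixed estrogen lists the E2 effect per pair of arrays (induced minus repressed genes) was 1.33 ± 0.03 (log2, SD, n = 3) in control cells, 1.20 ± 0.03 (n = 3, two-sided exact permutation p = 0.1, the smallest possible) with SAFB1 siRNA, 1.36 ± 0.07 (n = 4, exact p = 0.514) with SAFB2 siRNA and 0.59 ± 1.20 (n = 4, exact p = 0.486) with both siRNAs.

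With both siRNAs 1 pair stood apart. Of the arrays with title numbers 15 and 16, that labelled as given E2 had lower estrogen-induced and higher estrogen-repressed genes than its untreated partner. These arrays share a run but not a replicate letter (D for 15 and C for 16). The effect was −1.25, where the other 3 pairs lay between 1.05 and 1.34. Of the 78 genes, 0 had the sign seen in control cells. Without this pair the effect was 1.21 ± 0.15 (n = 3, exact p = 0.2), the slope was 0.85 and E2 changed 235 genes with both siRNAs, 342 in control cells, 237 with SAFB1 siRNA and 461 with SAFB2 siRNA. Adjusted over the 78 genes alone, 5 interactions of E2 with both siRNAs passed with all arrays and, over the 342 genes then called, 0 in limma (14 at an unadjusted p under 0.05) without the pair. With a run term too, 1195 genes were called in control cells. Over these, 1 interaction passed with SAFB1 siRNA (limma adjusted p = 0.0182, 187 at an unadjusted p under 0.05). For SAFB2 and both siRNAs 0 passed in limma (87 and 88 at an unadjusted p under 0.05). Leaving out 1 array, 38 genes passed with both siRNAs without the array of title number 15 (both siRNAs, replicate D) and 21 without that of 16 (both siRNAs with E2, replicate C). For SAFB1 siRNA 0 genes passed in limma without any 1 of SAFB1 replicates A, B, C and D and SAFB1 with E2 replicates B, C and D (704, 803, 946, 955, 769, 791 and 785 at an unadjusted p under 0.05). For SAFB2 siRNA 82, 74, 103 and 118 genes passed without SAFB2 replicates A, B, C and D, and 90, 104, 102 and 108 without SAFB2 with E2 replicates A, B, C and D. A term for the run gave 325, 894 and 0 genes (649 at an unadjusted p under 0.05) for SAFB1, SAFB2 and both siRNAs in limma. Without title numbers 17 to 19 it gave 0 (1795), 1082 and 0 (781). In the runs that hold all 8 groups, which leave out title numbers 15 and 16 too, it gave 302, 421 and 369.

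**Figure D3:**
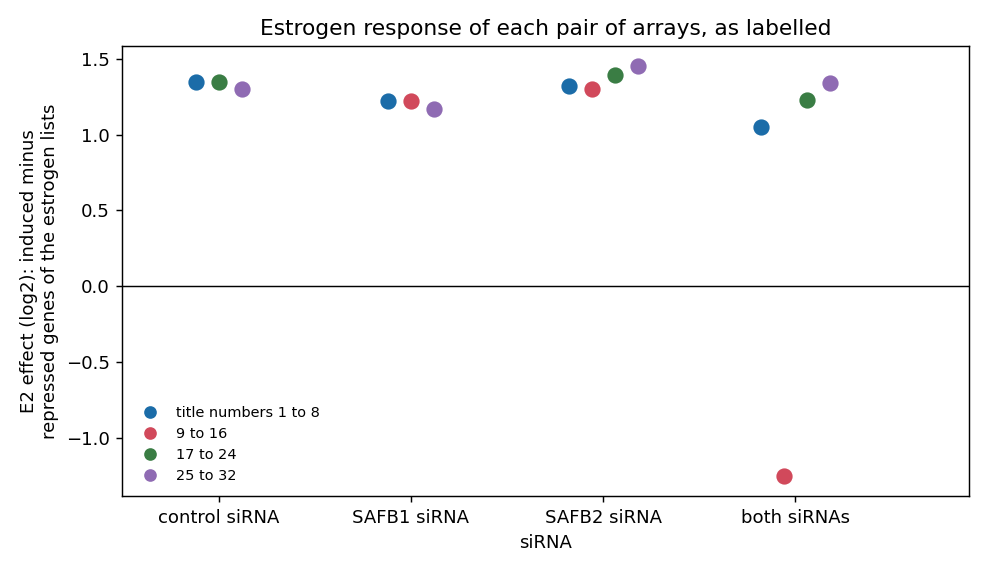
E2 effect on the fixed estrogen lists (vertical axis, log2, mean of induced genes minus mean of repressed genes) for each pair of an E2-treated and an untreated array, by siRNA (horizontal axis) and coloured by run of title numbers. Points are pairs; the pair of title numbers 15 and 16 lies at −1.25 and the other pairs with both siRNAs lie between 1.05 and 1.34.

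RNA quality and traces of other cells were compared between the siRNAs and control. The difference between the 3-prime and 5-prime actin probe sets, a sign of RNA integrity, was 0.01 higher than in control with SAFB1 siRNA, 0.10 with SAFB2 siRNA and 0.07 with both (two-sided exact permutation p = 0.939, 0.444 and 0.575, n = 7, 8 and 8 against 6). The run that holds no control array had the highest mean of this value, 0.88. Without that run the differences from control were −0.14, 0.004 and −0.013 (exact permutation p = 0.329, 0.985 and 0.926). Leukocyte and stromal markers, which MCF-7 cells should lack, differed from control by −0.09 with each siRNA treatment (exact p = 0.0892, 0.0806 and 0.0323), with an adjusted p of 0.268 over 9 comparisons. Ribosomal protein genes differed by −0.02, 0.00 and −0.04 (exact p = 0.339, 0.887 and 0.124). Between arrays of the same run and treatment, both siRNAs were below control in 6 of 6 pairs for ribosomal genes (−0.09 to −0.01) and in 6 of 6 for the leukocyte and stromal markers (−0.20 to −0.01). The exact permutation p within pairs was 0.0312 for each, with an adjusted p of 0.14 over 9 comparisons.

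**Figure D4:**
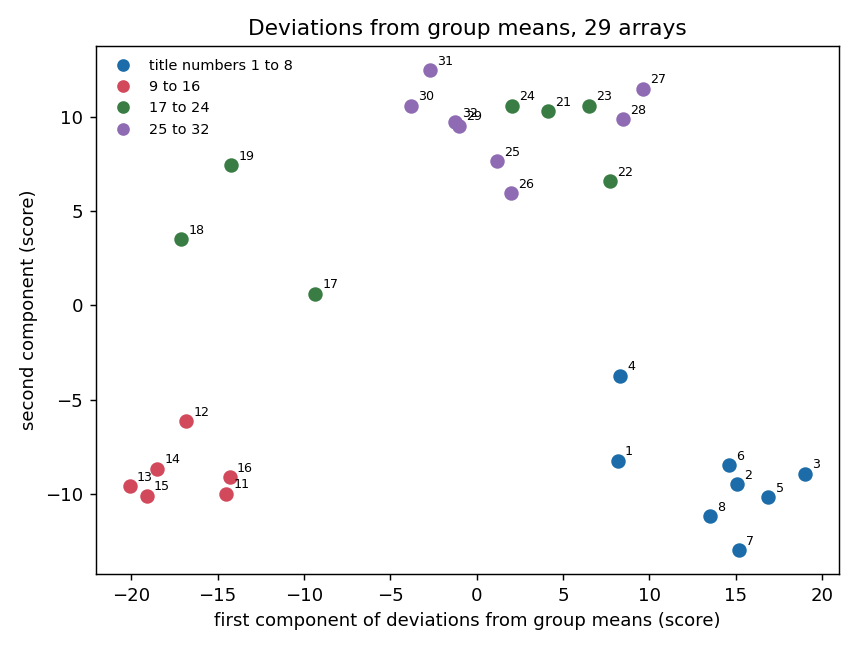
First (horizontal axis) and second (vertical axis) principal component scores of the 29 arrays after subtraction of group means, with points labelled by title number and coloured by run. The first component held 39% of this variance, of which 78.1% lay between the 4 runs.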

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

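The tests of the exchanged labels, of a fault of the run and of a lost response, and those of missing controls, of a shift within runs and of the siRNA itself, were chosen only after the result was seen; the tests of RNA quality, scaling and single control arrays and the other splits of the samples were set earlier. Outliers were sought in 52 sets of 4 values, of which 4 held one, and chance alone gives about 1 in 20.

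The E2 effect on the fixed estrogen lists with both siRNAs had 1 outlying pair, at −1.25 where the nearest pair had 1.05 (gap over range 0.888). A fault of the whole run is argued against by the other pairs of title numbers 9 to 16, of which the lower had an effect of 1.22, and a lost response with both paralogs reduced by the other pairs with both siRNAs, of which the lowest had 1.05. A candidate explanation is an exchange of the 2 labels, made before or after hybridisation. On 174 E2-regulated genes outside the lists, chosen in cells with SAFB2 siRNA, the difference of the pair with its labels exchanged was 0.943 of that in the rest of the run. Each array lay nearer the arm opposite to its label (2.14 for array 15 against an E2 mean of 2.19, and 1.46 for array 16 against an untreated mean of 1.47). The pair was already known to be reversed over all genes (r = −0.744 with the E2 effect of the other siRNAs), so a positive ratio was given in advance. Title numbers 13 and 14, in the rest of the run, also served to choose the 174 genes. The labels were kept as deposited in every count.

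Within groups the arrays parted by runs of title numbers: the first component of the deviations from group means held 39% of their variance, of which 78.1% lay between runs. Differences in RNA quality are argued against as the cause, since 70.7% still lay between runs with the 3-prime to 5-prime values of actin and GAPDH as covariates, and so is array-wide scaling, since the array medians averaged 8.26 to 8.27 in each run and 78.3% did after quantile normalization, which moved values by only 0.02 on average. A batch of culture, labelling or hybridisation may stand behind the runs and was not tested further, as the labels give no dates. No biological explanation was tested.

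Interferon-response genes were higher on average by 0.60 with SAFB1 siRNA, 0.37 with SAFB2 siRNA and 0.59 with both. The missing control arrays of title numbers 9 to 16 are argued against as the cause by the differences within the other runs, of which the lowest was 0.26, and a single outlying control array by leaving each out, which kept at least 92.5% of each difference. A response to the siRNAs themselves could also raise interferon genes and cannot be told apart from the loss of SAFB proteins, because each target had a single pool and the lowest difference of the siRNA treatments was 0.37. A shift of the last 4 numbers of a run that adds alike whatever the siRNA is argued against by both siRNAs minus SAFB1 siRNA, which spans the same parts and had a highest run mean of 0.03, below the lowest of SAFB2 siRNA minus control (0.26). The loss of a SAFB corepressor stays open, as does a shift that acts differently with SAFB1 siRNA.

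The actin 3-prime minus 5-prime difference of 1 untreated array with SAFB1 siRNA was 0.916, with the nearest at 0.417 (gap over range 0.852). This array has title number 11, and all arrays with title numbers 11 to 16, its run, lay between 0.81 and 0.96. The other runs averaged 0.41 to 0.56. The value is therefore the level of its run and not peculiar to the array. Antigen-presentation genes had a mean of 10.97 in 1 untreated array with SAFB2 siRNA, with the nearest at 11.19 (0.864). Cholesterol synthesis genes had a mean of 10.2 in 1 untreated array with both siRNAs, with the nearest at 10.33 (0.933). The effect of SAFB1 siRNA differed between cells with and without SAFB2 siRNA for 68 genes in limma, as the test of the interaction showed.

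The same arrays were also split in other ways, up to 100 splits each with the real one included. For called genes, 1 of 100 splits, the real one, gave as many for SAFB1 siRNA (1041, highest other 802), SAFB2 siRNA (197, highest other 85), both siRNAs (909, highest other 293) and the interaction of the paralogs (68, highest other 3). That share is under 0.05 and for SAFB1, SAFB2 and both siRNAs argues against chance, among splits that ignore the runs. For the interaction the splits mix all siRNA groups, which moves the effects of the siRNAs into the spread. They would give few calls with or without an interaction, so they cannot tell whether the 68 genes arose by chance. The splits with 802 and 293 nearly exchange the compared groups. For SAFB1 against SAFB2 siRNA 2 of 100 did (196), also a share under 0.05, but another split gave more genes (285). The split with 285 parts title numbers 17 to 32 from 1 to 16 and so follows the runs; with a term for the run 972 genes passed. For E2 the share was under 0.05 with SAFB1 siRNA (1 of 35 splits, 32 against 0) and SAFB2 siRNA (1 of 35, 191 against 0). With SAFB1 siRNA the genes lay at the threshold (smallest limma adjusted p = 0.0489). Without any 1 of its 7 arrays 0 passed in limma (704 to 955 at an unadjusted p under 0.05). In control cells the 10 splits are too few for a share under 0.05 (real 78 genes, 1 of 10, highest other 28; real 7 lists, 3 of 10, highest other 7). Where 0 genes passed in limma (228, 140, 155 and 145 at an unadjusted p under 0.05) every split gives as many, so the splits say nothing about chance: E2 with both siRNAs (35 of 35 splits, highest other 433), and E2 by SAFB1 (100 of 100, highest other 2088), by SAFB2 (100 of 100, 5) and by both siRNAs (100 of 100, 289). The split with 433 exchanges the 3 other pairs and so lines them up with title numbers 15 and 16. That with 289 mixes control and both siRNAs in untreated cells alone, so that the siRNA effect left in E2-treated cells appears as an interaction. That with 2088 sets title numbers 1 to 4, 27 and 28 against 11, 12, 17 to 19, 25 and 26. This parts the arrays by the first component of the deviations from group means (8.16 to 19 against −17.1 to 1.97), which lay mostly between runs. Counts this far above the real ones point to a structure of the samples. For lists passed with the preset correlation chance cannot be excluded: 5 of 100 splits gave as many for SAFB1 siRNA (14, highest other 16), 11 of 100 for SAFB2 siRNA (9, highest other 14) and 6 of 100 for both siRNAs (14, highest other 15). The median of the other splits was 6, 4 and 6 lists, so a pass with the preset correlation is weak evidence by itself.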

How the results depend on the processing

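The run term's use for lists, overlaps and slopes, the settings without title numbers 15 and 16 or 17 to 19, the half-run term (4 consecutive numbers), the complete runs, the single runs and the pairs within runs were chosen after seeing the data. Of 410 values that answer a comparison, 285 were kept and 125 were not. Tests had to keep their direction and side of the threshold, and counts had to lie within 1.5 times. E2 slopes had to move by less than the SD between pairs (0.04, 0.033 and 0.84 for SAFB1, SAFB2 and both siRNAs). With both siRNAs the move from 0.414 to 0.85 without title numbers 15 and 16 therefore counts as kept. Quantile normalization, centring on medians, the offset, and trend with robust changed none of these. Of 225 named-gene results 1 reversed, H3C2 with SAFB1 siRNA at −0.01 in title numbers 17 to 24 alone, which hold 1 SAFB1 siRNA array. Each kept its side with the run term, and 60 lost it without some single array. Of 88 list results 31 were lost with an estimated correlation, 13 without dim genes, 4 with quantile normalization and 2 with the run term. Unless a cause is named, the cause was not tested. Fewer arrays, or in the runs alone fewer arrays and another spread, go with the settings that leave arrays out.

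With a term for the replicate letter, whose arrays resembled each other less than those of a run (median correlation 0.323 against 0.5), the counts were 386 for SAFB2 siRNA, 376 for SAFB1 against SAFB2, 141 for the paralog interaction, 103 for E2 with SAFB1 siRNA and 412 for E2 with SAFB2 siRNA. With the run term they were 2935 for SAFB1 siRNA, 2570 for SAFB2 siRNA, 3485 for both, 972 for SAFB1 against SAFB2, 410 for the interaction, and for E2 680 in control cells, 325 with SAFB1 siRNA and 894 with SAFB2 siRNA. Shared higher genes were then 873 for SAFB1 and SAFB2 siRNA, 1269 for SAFB1 and both, and 1078 for SAFB2 and both. The E2 slopes were 0.747 (SAFB1) and 0.87 (SAFB2). The term takes the difference between runs out of the spread. With the controls divided, fewer arrays per comparison, the shared higher genes were 59.7, 202 and 60.4. With the fixed estrogen lists the slopes were 0.895 and 0.975.

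Without dim genes 9 lists passed for SAFB1 siRNA and 4 for E2 in control cells. With an estimated correlation 5, 3, 5 and 0 lists passed for SAFB1, SAFB2, both siRNAs and E2 in control cells. With every probe set tested the counts were 298 for SAFB2 siRNA, 298 for SAFB1 against SAFB2 and, in limma, 0 for E2 with SAFB1 siRNA (1430 at an unadjusted p under 0.05). With the mean of a gene's probe sets the last was also 0 in limma (887 at an unadjusted p under 0.05). With array weights, whose estimation stopped early with a warning (the weights of limma's gene-by-gene method correlated with them at 0.979 on the log scale), the counts were 1821, 684 and 1827 for SAFB1, SAFB2 and both siRNAs. They were 483 for SAFB1 against SAFB2, 153 for the interaction, and for E2 497 in control cells and 186, 575 and 136 with SAFB1, SAFB2 and both siRNAs. At 1.5-fold or more, which leaves fewer genes by construction, they were 232, 66, 205, 34 (SAFB1 against SAFB2) and 123 (E2 with SAFB2 siRNA). The target values of SAFB2, 0.40 with SAFB1 siRNA, −0.53 with SAFB2 siRNA and −0.42 with both, did not reach it. With only the groups compared, E2 changed 143 genes in control cells and 91 with SAFB1 siRNA.

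In untreated cells alone, with fewer arrays, the counts were 294, 37 and 145 for SAFB1, SAFB2 and both siRNAs, 6 for SAFB1 against SAFB2 and 19 for the interaction. There SAFB2 differed by 0.34 with SAFB1 siRNA (limma adjusted p = 0.111) and −0.41 with both (0.0661). In E2-treated cells alone they were 330, 78, 472, 9 and 12. The other SAFB probe sets gave −0.47 and −0.03 with SAFB1 siRNA and −0.48 and −0.10 with both, and the other SAFB2 probe set 0.04 with SAFB1 siRNA. With the run term the first of these SAFB probe sets passed, at −0.39 with SAFB1 siRNA (limma adjusted p over all probe sets = 0.00718) and −0.38 with both (0.0051).

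Without title numbers 15 and 16 E2 changed 342 genes in control cells and 237, 461 and 235 with SAFB1, SAFB2 and both siRNAs. With the run term and without that pair the counts were 3216, 2835 and 3347 for SAFB1, SAFB2 and both siRNAs, 1224 for SAFB1 against SAFB2, and 485 for the interaction. For E2 they were 1195, 795, 1270 and 875, with slopes of 0.751 (SAFB1) and 0.87 (SAFB2), or 0.84 and 0.975 on the fixed lists. With the half-run term they were 3366 for SAFB1 siRNA, 757 for the interaction, and for E2 1329, 332 and 1368 in control cells, SAFB1 and SAFB2 siRNA. SAFB2 siRNA and both siRNAs against control, and SAFB1 against SAFB2, could not be estimated, because these siRNAs never share such a block. In the complete runs with the run term they were 2327, 408 (SAFB2 siRNA), 402 (SAFB1 against SAFB2), 150 (interaction), and for E2 442, 302, 421 and 369. With the run term and without title numbers 17 to 19 they were 2781, 958 and 2288, 796 (SAFB1 against SAFB2) and 537 (interaction). For E2 they were 1 in control cells, 0 in limma with SAFB1 siRNA (1795 at an unadjusted p under 0.05) and 1082 with SAFB2 siRNA. The complete runs hold fewer arrays still, without title numbers 15 and 16, and gave 442 in control cells and 302 with SAFB1 siRNA. Fewer arrays alone therefore do not account for the counts of 1 and 0.

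In single runs SAFB1, SAFB2 and both siRNAs changed 2090, 2631 and 3159 genes in title numbers 1 to 8 and 3306, 534 and 1893 in 25 to 32, SAFB1 siRNA 86 in 17 to 24. SAFB1 against SAFB2 gave 2170, 0 in limma (748 at an unadjusted p under 0.05), 2 and 1436 in the 4 runs in order of number, and the interaction 0 in limma in 17 to 24 (358) and 675 in 25 to 32. In 17 to 24 SAFB differed by −0.86 with SAFB1 siRNA (limma adjusted p = 0.0589) and SAFB2 by 0.19, −0.55 and −0.43 with SAFB1, SAFB2 and both siRNAs (0.805, 0.0574 and 0.0594). Ribosomal protein genes with both siRNAs differed by −0.052 without title numbers 9 to 16 (exact permutation p = 0.0195, not adjusted) and by −0.052 in pairs within runs (exact permutation p = 0.0312, not adjusted).

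Without 1 array at a time the counts ranged from 710 to 1108 for SAFB1 siRNA, 121 (without control replicate B) to 234 for SAFB2 siRNA, 618 to 1148 for both, 110 (without SAFB1 with E2 replicate B) to 228 for SAFB1 against SAFB2 and 44 (without control B) to 71 for the interaction. For E2 they ranged from 0 (without control with E2 replicate A, 827 at an unadjusted p under 0.05 in limma) to 10 in control cells and were 0 in limma with SAFB1 siRNA without each of its 7 arrays (704 to 955). They ranged from 74 to 118 with SAFB2 siRNA and 0 to 38 (without both replicate D) with both. The E2 interactions stayed at 0. Lists ranged from 11 to 16, 6 to 12, 12 to 14 and 5 to 10 for SAFB1, SAFB2, both and E2 in control cells. Slopes ranged from 0.789 to 0.844, 0.901 to 0.947 and 0.332 to 0.634 with SAFB1, SAFB2 and both siRNAs, and shared higher genes from 102 to 169, 373 to 548 and 106 to 187. SAFB fell by 0.86 to 1.00 with SAFB1 siRNA and by 0.93 to 1.06 with both, and SAFB2 from 0.37 to 0.43, −0.56 to −0.49 and −0.44 to −0.39 with SAFB1, SAFB2 and both.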
